A study of Mus musculus with 6 samples.

How the data were processed

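RNA was purified from Nutlin-treated MA9 leukaemia cells of the genotypes Gata2 f/f and Gata2 KO, and libraries were made from poly(A)-selected RNA with a NEBNext Ultra II kit and sequenced as paired-end reads of 90 bp, per the labels' protocols. The authors deposited a single table of whole-number counts per gene, not normalised, with 1 column per sample and Ensembl gene identifiers with versions. The submitters' processing notes name kallisto, HTSeq, DESeq2 and the genome build mm10, with no role, order or version; which of the first pair gave the counts, the annotation and whether strand was used are not given in the sources used here. Counts of overlapping, antisense and near-identical genes can therefore be shared or split. Of the 49585 identifiers, 43749 matched the reference gene names of GENCODE release M21 (GRCm38, the assembly of mm10) exactly and 49326 matched without the version; the unmatched rows held 0.00962% of the counts. Symbols were taken from that match and coordinates from the same annotation. No column of per-sample values was left unused.

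The genotype and the number of each sample were taken from its title. The series' design text describes the 3 samples of each condition as independent, but not whether they were separate leukaemias or cultures of one, so p-values measure the spread between these samples. No libraries were duplicates: over genes, the chi-square per degree of freedom was at least 35.5 between any pair of libraries, that of Gata2 f/f 1 and the library labelled Gata2 KO 2, and at least 93.8 between libraries of one group. Without 4 genes that carry ribosomal RNA reads, abundant in both libraries of the closest pair, the smallest was 27.3, between Gata2 f/f 2 and the library labelled Gata2 KO 2. Total counts ran from 17138687 to 26440960 per library. All counts are of reads without molecular identifiers.

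Genes were kept by edgeR's filterByExpr (minimum count 10), which left 13744 genes (27.7%) holding 99.9% of the counts. Library sizes were scaled by TMM, and Gata2 KO was compared with Gata2 f/f by edgeR's quasi-likelihood test with robust dispersion estimates, without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-scaled CPM values computed from the deposited counts, given as mean ± SD over 3 libraries, and fold changes are log2 of Gata2 KO over Gata2 f/f with the standard error from the F statistic. Log values for scores and principal components used a prior count of 2. The 34 gene lists (824 entries) were written before the data were examined and tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 33 lists with at least 3 tested genes. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

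The genes named were fixed by a rule before the data were examined: Gata2; the 12 genes of largest change in each direction among those past the threshold with at least 5 CPM in the higher group and non-overlapping ranges, leaving out predicted models and antigen receptor genes (0 genes met this); up to 4 members of smallest p of each list called by camera or holding a called gene; and Cdkn1a, Mdm2, Bax, Bbc3, Pmaip1, Bcl2, Mcl1, Trp53, Mdm4, Myc, Hoxa9, Meis1, Kit, Cd34 and Itgam. Other genes are said to be chosen after their values were seen.

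Whether equal numbers pair the samples was checked before the fits were compared. The deviations of log2 CPM from the group means correlated between the f/f and KO libraries of number 1 at 0.29, of number 2 at 0.55 and of number 3 at 0.65, all over 0.1, so by the rule set beforehand the numbers were taken to pair the samples. Unlike numbers met the same bound between f/f 1 and KO 2 (0.46, above the 0.29 of number 1) and between f/f 2 and KO 1 (0.104), so the check sets number 3 apart but does not show that numbers 1 and 2 pair their own samples. The labels do not say what a number stands for. The fit with the number as a block has 2 residual degrees of freedom, against 4 without it, and its biological coefficient of variation was 0.256, against 0.426.

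The other settings were DESeq2's size factors and upper-quartile scaling, no filter on low counts, a mean CPM of at least 1, DESeq2, limma voom, the replicate block, a threshold of 0.01, a test against a 1.5-fold change, and leaving out each library in turn. The fits with DESeq2 and the block, without the library labelled Gata2 KO 2, without both libraries numbered 3, without 4 genes that carry ribosomal RNA reads, and without the library labelled Gata2 KO 2 with Gata2 taken out of the lists were added after the data were seen. On simulated counts for the 13744 genes of this comparison, drawn from the real means and library sizes, edgeR without the block called 5% of genes changed 2-fold, 42.5% of those changed 4-fold and 87.5% of those changed 8-fold; with the block it called 33.8%, 87.5% and 97.5%. Among the unchanged simulated genes edgeR called 11 without and 13 with the block, and DESeq2 51 and 25.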

Results

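Poly(A) RNA was sequenced from mouse bone marrow leukaemia cells called MA9 in the labels, a usual short name for leukaemias driven by the MLL-AF9 fusion. The cells carried either loxP-flanked Gata2 alleles (Gata2 f/f) or a Gata2 deletion (Gata2 KO). The sample descriptions name the Gata2 KO samples Cre and the others f-f, so Cre and the deletion go together by label. Their effects cannot be told apart here. Gata2 is a zinc-finger transcription factor of blood stem and progenitor cells. All 6 cultures, 3 per genotype and numbered 1 to 3, had been kept for 18 h in 5 uM Nutlin, a small molecule that blocks the binding of MDM2 to p53 and so stabilises p53. Cultures without Nutlin were not analysed here, so no effect of Nutlin itself was measured. The deposited table held 49585 genes, and the total count per library ran from 17138687 to 26440960. In the Gata2 f/f libraries 1, 2 and 3 it was 17138687, 21203874 and 25158033, and in those labelled Gata2 KO 1, 2 and 3 it was 20229820, 18651102 and 26440960. The design poses a single question: how the transcriptome of Nutlin-treated leukaemia cells differs between the genotypes.

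Gata2 transcripts were low in 2 of the 3 libraries labelled Gata2 KO and high in the remaining one. Gata2 (ENSMUSG00000015053.14, protein-coding, GRCm38 chromosome 6, 88193891 to 88207032, plus strand) had 33.6, 22.3 and 18.4 CPM, counts scaled to the normalised library size, in Gata2 f/f 1, 2 and 3. It had 5.44 and 4.33 CPM in the libraries labelled Gata2 KO 1 and 3, and 43.3 CPM in the library labelled Gata2 KO 2, above every f/f library. The raw counts behind these values were 590, 500 and 463 in Gata2 f/f and 114, 797 and 103 in Gata2 KO. The means were 24.8 ± 7.91 CPM in Gata2 f/f and 17.7 ± 22.2 CPM in Gata2 KO (SD, n = 3 each), a log2 fold change of -0.49 ± 0.86 (SE), which did not pass edgeR's quasi-likelihood test (adjusted p = 1.00 over all genes). The library labelled Gata2 KO 2 therefore goes against its label at the targeted gene, and every direction below that rests on the 3 libraries labelled KO includes it. Counts per gene cannot show whether the transcripts came from an intact or a deleted allele. Without that library the log2 fold change was -2.35 with no block (edgeR, adjusted p = 0.915). It was -2.36 with the replicate number as a block (adjusted p = 0.00356), an alternative chosen after the data were seen. That library was left out for its Gata2 level, so a lower Gata2 value followed from the choice. The adjusted p without it is therefore no evidence of Gata2 loss.

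Cd34, a surface marker of blood progenitors, had the same layout as Gata2. It lay at 35.1, 39.2 and 33.6 CPM in Gata2 f/f, at 4.68 and 6.68 CPM in the libraries labelled Gata2 KO 1 and 3, and at 37.1 CPM in that labelled Gata2 KO 2. Its log2 fold change was -1.16 ± 0.74 and did not pass edgeR's test, while DESeq2 with the block called it (-1.82, adjusted p = 0.00153). Kit, the stem cell factor receptor, had 28.5 to 88.7 CPM in Gata2 f/f, 59.7 and 58.0 CPM in KO 1 and 2, and 1.34 CPM in KO 3. Hoxa9 and Meis1, homeobox genes active in MLL-fusion leukaemias, were at 173 ± 5.39 and 57.0 ± 16.0 CPM in Gata2 f/f and at 212 ± 17.4 and 64.6 ± 5.46 CPM in Gata2 KO. The log2 fold changes were 0.29 ± 0.20 for Hoxa9 and 0.18 ± 0.26 for Meis1, and neither passed the test. The list of 23 tested MLL fusion targets (camera, adjusted p = 0.904) and that of 23 stem and progenitor transcription factors (adjusted p = 0.753) were not called. Without the library labelled Gata2 KO 2, camera called the stem and progenitor list downward (adjusted p = 0.0184; adjusted p = 0.698 with an estimated correlation). The list holds Gata2, the gene for which that library is doubted, and with Gata2 taken out it was not called (adjusted p = 0.104), but was with the block as well (adjusted p = 0.0234; adjusted p = 0.764 with an estimated correlation). Over each library left out in turn its adjusted p ran from 0.0184 to 0.880.

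**Figure D1:**
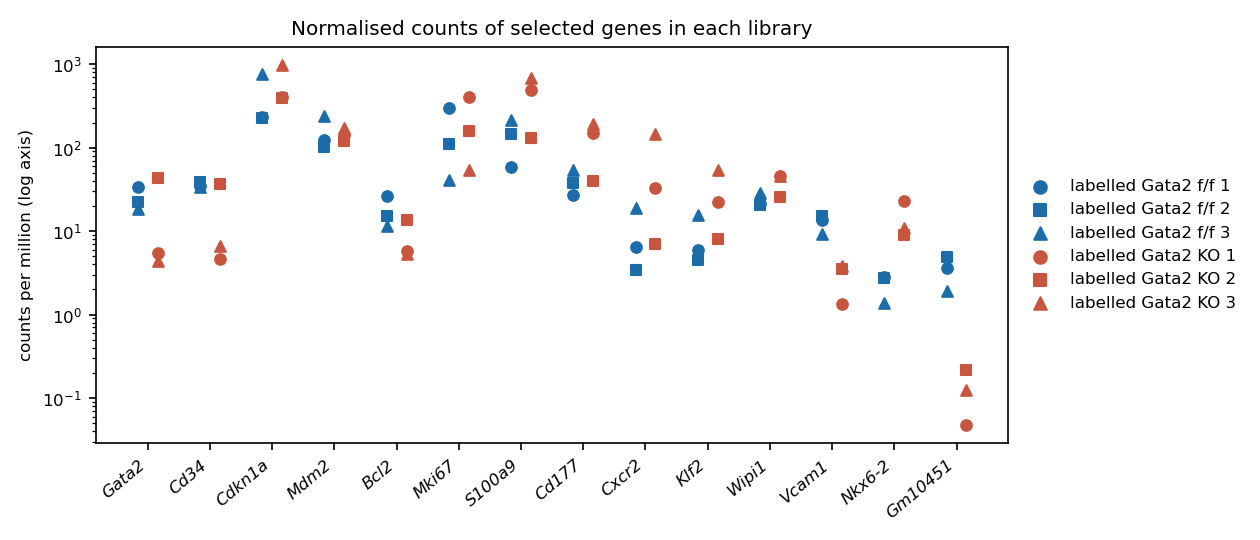
Normalised counts of 14 genes in each library, in CPM on a log axis; colour gives the genotype on the label and the symbol the library number. Gata2 and Cd34 of the library labelled Gata2 KO 2 (43.3 and 37.1 CPM) lie at the level of the Gata2 f/f libraries, while Vcam1, Nkx6-2 and Gm10451 separate the 3 libraries of each label. Vcam1, Nkx6-2 and Gm10451 were called by DESeq2 with the library labelled Gata2 KO 2 counted as Gata2 KO.

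Across the transcriptome, the libraries labelled Gata2 KO had higher values for genes of mature myeloid cells and for immediate early, inflammatory, interferon response and lysosomal genes. They had lower values for genes of DNA repair, DNA replication and ribosome biogenesis. No single gene passed the threshold in the unblocked edgeR test. Of the 34 gene lists fixed before the data were examined, 33 had at least 3 tested members. Camera with a preset inter-gene correlation of 0.01 called 14 of them, 11 upward and 3 downward. None of the 14 held with an estimated correlation (adjusted p = 0.856 for each). Of the 14 calls, 12 were lost without Gata2 KO 3, 12 without Gata2 f/f 1, 7 without Gata2 f/f 2, 2 without Gata2 KO 1, and 1 each without the library labelled Gata2 KO 2 and without Gata2 f/f 3. These fits had no block, so each left the numbers unequal between the genotypes, and a lost call can also reflect the number. No member of any list was called by edgeR over all genes tested, and none was called when adjusted over the list alone. With the replicate block, edgeR called none over all genes, while adjusted over the list alone 7 of 21 late neutrophil, 6 of 31 monocyte and macrophage, 3 of 7 cyclin-dependent kinase inhibitor, 3 of 23 immediate early, 3 of 11 megakaryocyte, 2 of 48 p53, 2 of 13 dendritic, 2 of 28 lysosome and 1 of 22 interferon genes were. DESeq2 with the block, chosen after the data were seen, called list members over all genes, among them 9 late neutrophil, 7 monocyte and macrophage, 3 lysosome, 2 dendritic and 2 p53 genes, all higher in Gata2 KO, and 1 p53 gene lower.

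Among the 33 lists tested, the late neutrophil list had the largest shift. Of its 21 tested genes, 20 had a positive log2 fold change, with a median of 1.16 (camera, adjusted p = 2.86e-07; adjusted p = 0.856 with an estimated correlation). Cd177, a neutrophil surface glycoprotein, was at 39.7 ± 14.0 CPM in Gata2 f/f and 127 ± 78.0 CPM in Gata2 KO (log2 fold change 1.68 ± 0.56). S100a9, a calcium-binding protein abundant in neutrophils, was at 139 ± 77.5 and 438 ± 285 CPM (1.66 ± 0.68). The chemokine receptor gene Cxcr2 (2.66 ± 1.10) and the granule protein gene Ngp (1.16 ± 0.49) also had positive values, and none of the 4 passed edgeR's gene-level test, with or without the block. DESeq2 with the block called Cxcr2 (adjusted p = 3.22e-07), Cd177 (0.00560) and Ngp (0.0382), and not S100a9 (0.547). Without Gata2 KO 3 the log2 fold change of Cxcr2 was 1.03. The list also followed the library number. Its score was 1.03 in Gata2 f/f 3, above the 0.61 of KO 1, 1.83 in KO 3 and -0.75 in the library labelled KO 2, and 10 of the 21 genes were called between numbers, all higher in number 3. S100a9 was at 494 and 692 CPM in the libraries labelled KO 1 and 3, but at 130 CPM in KO 2, within the Gata2 f/f range of 58.4 to 213 CPM. Between libraries of the same number, the mean log2 difference of the list was 2.05 for number 1, 0.51 for number 2 and 0.80 for number 3. Without Gata2 KO 3 the list lost its call (adjusted p = 0.0938).

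Monocyte and macrophage genes (27 of 31 positive, median 0.42; camera, adjusted p = 0.00188) and genes of primary granules and granulocyte-monocyte progenitors (14 of 17 positive, median 0.27; adjusted p = 0.0397) were shifted upward too, each with adjusted p = 0.856 under an estimated correlation. The leading monocyte genes were the Fc receptor genes Fcgr4 (log2 fold change 1.20 ± 0.80) and Fcgr3 (0.96 ± 0.72; called by DESeq2 with the block, adjusted p = 0.0368), the endotoxin co-receptor Cd14 (0.96 ± 0.95) and, in the opposite direction, the chemokine receptor Cx3cr1 (-1.36 ± 1.12). Itgam, the integrin alpha M gene of myeloid cells, had 0.56 ± 0.88. Without the block, each of these directions turned when a single library was left out. Without Gata2 f/f 3 the log2 fold change of Cx3cr1 was 0.98. Without Gata2 KO 3 the values were -0.11 for Fcgr4, -0.038 for Fcgr3, -0.26 for Cd14 and -0.43 for Itgam. Those fits keep only 1 library numbered 3, so the turns can also follow from the difference between numbers. Within numbers 1, 2 and 3 the log2 differences were 1.20, 0.35 and 1.05 for Fcgr3 and 0.23, 1.64 and 0.91 for Cd14. They were 1.29, -0.019 and 1.51 for Fcgr4, and 0.59, 0.0030 and -1.99 for Cx3cr1. Prtn3, which encodes proteinase 3, was at 1096 ± 238 CPM in Gata2 f/f and 1556 ± 372 CPM in Gata2 KO, and Fcnb, encoding ficolin B, had 6.30 CPM in KO 1 and 0.60 to 0.88 CPM in the other 5 libraries. Both libraries numbered 3 also lay apart from the other 4 in these lists, above them in monocyte and macrophage genes and narrowly below them in primary granule genes. The monocyte and macrophage score was 1.49 in Gata2 f/f 3 and 1.68 in Gata2 KO 3, against -1.45 to -0.10 in the other 4, and the primary granule score was -0.347 and -0.146, against -0.124 to 0.566. Without Gata2 KO 3 the monocyte and macrophage list turned downward (adjusted p = 0.505), and without Gata2 f/f 1 or 2 it was uncalled (0.361 and 0.363). Its mean log2 differences within numbers 1, 2 and 3 were 1.12, 1.06 and 0.19. The primary granule list was uncalled without Gata2 KO 1 (0.704), f/f 1 (0.168) or f/f 3 (0.632).

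**Figure D2:**
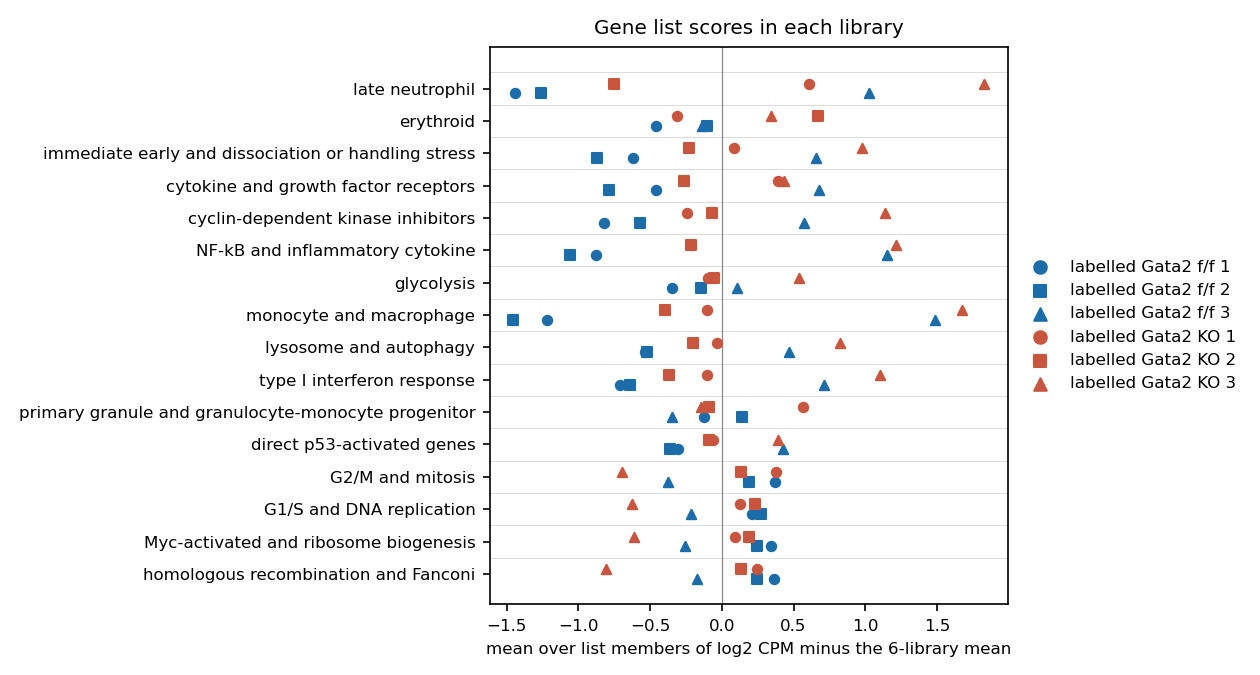
Scores of 16 gene lists in each library: the mean over list members of log2 CPM minus the 6-library mean, with 1 row per list. The lists are the 14 called by camera, the direct p53-activated genes and the G2/M genes. The triangles, libraries numbered 3, lie to one side of the other 4 libraries in the monocyte and macrophage row (1.49 and 1.68) and in the late neutrophil row (1.03 in f/f 3 and 1.83 in KO 3, next to 0.61 in KO 1).

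Immediate early, lysosomal, inflammatory, interferon response and cytokine receptor genes made up most of the other upward lists. The immediate early list had 21 of 23 members with positive values (median 0.45, camera adjusted p = 0.000443), led by the transcription factor genes Klf2 (log2 fold change 1.71 ± 0.76) and Fosl1 (1.07 ± 0.61). The lysosome and autophagy list had 25 of 28 (median 0.42, adjusted p = 0.000468), with Wipi1, an autophagosome protein gene, at 23.2 ± 4.40 and 39.1 ± 11.5 CPM, and the acid alpha-glucosidase gene Gaa at 142 ± 19.0 and 188 ± 30.5 CPM. NF-kB and inflammatory cytokine genes had 24 of 26 (adjusted p = 0.00208; Bcl3 0.93 ± 0.62 and Zfp36 0.54 ± 0.39). Type I interferon response genes had 20 of 22 (adjusted p = 0.0132; Zbp1 1.23 ± 0.77 and Xaf1 1.29 ± 0.98). Cytokine and growth factor receptors had 16 of 20 (adjusted p = 0.00798), although the leading member, the progenitor receptor Flt3, went the other way (-1.82 ± 1.07), followed by Tnfrsf1a (0.48 ± 0.33). The 20 glycolysis genes had 16 positive values (adjusted p = 0.0112). Its leading member, the glucose transporter Slc2a3, was lower in every library labelled KO (2.27 to 3.15 CPM, against 3.54 to 9.50 CPM), while hexokinase Hk1 had 0.56 ± 0.27. Erythroid genes were shifted upward (8 of 9 positive, adjusted p = 0.00964) at low levels, with Hbb-bs at 0.99 ± 0.28 and 2.52 ± 1.35 CPM and Hba-a1 at 0.97 ± 0.50 and 1.90 ± 0.57 CPM. Hba-a1 has a near-identical paralogue, so its count is uncertain. The libraries numbered 3 stood apart in several of these lists. Scores in Gata2 f/f 3 were 0.65 for immediate early, 1.15 for NF-kB and 0.72 for interferon genes, above those of the libraries labelled KO 1 (0.08, -0.21 and -0.11) and KO 2 (-0.23, -0.22 and -0.36). Between numbers, 12 of 23 immediate early, 15 of 26 NF-kB and 8 of 22 interferon genes were called, all higher in number 3. Within each number the means of these lists were higher in the KO library, with mean log2 differences for numbers 1, 2 and 3 of 0.70, 0.64 and 0.32 (immediate early), 0.66, 0.84 and 0.06 (NF-kB), 0.60, 0.28 and 0.39 (interferon) and 0.50, 0.32 and 0.35 (lysosome). With the block, camera gave adjusted p = 2.30e-07, 1.27e-06, 0.000652 and 1.64e-07 for these 4 (adjusted p = 0.544 for each with an estimated correlation). DESeq2 with the block called Klf2 (adjusted p = 0.000227), Bcl3 (0.00862) and Zbp1 (0.0179). Without Gata2 KO 3 the log2 fold changes were 0.78 for Klf2, 0.36 for Fosl1, 0.47 for Bcl3, 0.13 for Zfp36, 0.37 for Zbp1, -0.13 for Xaf1 and 0.21 for Tnfrsf1a, and without Gata2 f/f 1 that of Flt3 was -0.52. Each of these 7 lists had an adjusted p = 0.856 with an estimated correlation. Without Gata2 KO 3 all but the erythroid list were uncalled (adjusted p = 0.234 to 0.870), and without Gata2 f/f 1 all but the immediate early list (0.168 to 0.387). Without Gata2 f/f 2 the NF-kB (0.294), interferon (0.288), receptor (0.328) and immediate early lists (0.0522) were uncalled, without Gata2 KO 1 the receptor list (0.0580), and without the library labelled KO 2 the erythroid list (0.188).

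Genes that p53 activates directly were not called as a list in the unblocked test (32 of 48 positive, median 0.19, camera adjusted p = 0.156; 0.00123 without Gata2 f/f 3 and 0.870 without Gata2 KO 3). With the replicate number as a block they were called upward (adjusted p = 0.0272; adjusted p = 0.632 with an estimated correlation). All 7 cyclin-dependent kinase inhibitor genes had positive values (median 0.44, adjusted p = 0.00818; adjusted p = 0.856 with an estimated correlation, 0.688 without Gata2 KO 3 and 0.197 without Gata2 f/f 1), led by Cdkn1c (1.85 ± 0.75, at most 3.40 CPM) and Cdkn2d (0.71 ± 0.33). Cdkn1a, which encodes the p53-induced inhibitor p21, was at 233, 228 and 758 CPM in Gata2 f/f 1, 2 and 3 and at 404, 389 and 979 CPM in Gata2 KO 1, 2 and 3. It was thus higher in the KO library of each number, with an unblocked log2 fold change of 0.54 ± 0.59. With the block the log2 fold change was 0.64 ± 0.17 (edgeR, unadjusted p = 0.00683, adjusted p = 0.403). Mdm2, the p53 target that encodes its ubiquitin ligase, was at 154 ± 74.0 and 144 ± 26.1 CPM (-0.10 ± 0.36), Trp53 itself at 179 ± 12.5 and 188 ± 8.09 CPM (0.07 ± 0.20), and Mdm4 had -0.33 ± 0.38. Among apoptosis genes, Bax (0.45 ± 0.26) and Bbc3 (0.45 ± 0.29) had positive values, Pmaip1 was at -0.15 ± 0.35 and Mcl1 at 0.24 ± 0.35. Bcl2, the pro-survival gene, was at 17.8 ± 7.84 and 8.21 ± 4.56 CPM (-1.12 ± 0.48), and in the library labelled KO 2 it was at 13.5 CPM, inside the Gata2 f/f range of 11.5 to 26.6. No gene of this paragraph passed edgeR's test. The lists of pro-apoptotic (adjusted p = 0.0574; 0.0203 without Gata2 f/f 3 and 0.605 without Gata2 KO 3) and pro-survival genes (adjusted p = 0.684) were not called.

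The 3 downward lists were those of homologous recombination, of Myc-activated and of DNA replication genes. Homologous recombination and Fanconi genes had 5 of 29 positive values (median -0.23, camera adjusted p = 0.00212), with the checkpoint kinase Chek1 at 27.4 ± 6.80 and 18.7 ± 7.96 CPM and Xrcc2 at 27.8 ± 5.32 and 19.6 ± 8.17 CPM. Myc-activated and ribosome biogenesis genes had 6 of 35 (median -0.21, adjusted p = 0.00210), with Hspd1 at -0.55 ± 0.37 and Mat2a at -0.41 ± 0.27, while Myc itself had -0.12 ± 0.34. G1/S and DNA replication genes had 9 of 39 (median -0.18, adjusted p = 0.0218). Pola1, the catalytic subunit of DNA polymerase alpha, had -0.49 ± 0.40, and the leading member E2f2 went the other way (0.82 ± 0.29), with 68.5 to 112 CPM in the KO libraries and 38.1 to 57.6 CPM in Gata2 f/f. Mki67, a proliferation marker chosen after its values were seen, was instead higher in the KO library of each number (log2 differences 0.41, 0.51 and 0.42), with a blocked log2 fold change of 0.45 ± 0.14 (edgeR, unadjusted p = 0.0190, adjusted p = 0.418). The G2/M and mitosis list missed the threshold (11 of 40 positive, adjusted p = 0.0504) and was called with the block (adjusted p = 0.0272; adjusted p = 0.580 with an estimated correlation). The 3 downward lists also followed the library number. Homologous recombination scores were -0.18 in Gata2 f/f 3 and 0.24 and 0.14 in the libraries labelled KO 1 and 2. Those of Myc-activated genes were -0.26, 0.09 and 0.19, and of G1/S genes -0.22, 0.13 and 0.23. Mean log2 differences within numbers 1, 2 and 3 were -0.12, -0.11 and -0.63 (homologous recombination), -0.25, -0.06 and -0.36 (Myc-activated) and -0.08, -0.04 and -0.41 (G1/S). Each of the 3 downward lists had an adjusted p = 0.856 with an estimated correlation, and each turned upward, uncalled, without Gata2 KO 3 (adjusted p = 0.322 for G1/S, 0.870 for the other 2). That unblocked fit keeps Gata2 f/f 3, which scored low on these lists, so the turn can also follow from the library number. Without Gata2 f/f 1 all 3 were uncalled (adjusted p = 0.168 for each), as were G1/S (0.554) and Myc-activated genes (0.0509) without Gata2 f/f 2.

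Among markers of other cell types, dendritic cell and MHC class II genes (11 of 13 positive, adjusted p = 0.0527) and stroma and endothelium genes (10 of 13, adjusted p = 0.0684) were not called without the block and were called with it, at adjusted p = 0.00623 and 0.0388. The same held for antioxidant genes (15 of 22, adjusted p = 0.0622 and 0.0272). With an estimated correlation none of the lists called with the block held (smallest adjusted p = 0.544). The erythroid and the primary granule lists lost their call with the block (adjusted p = 0.0900 for both). Mast cell and basophil (adjusted p = 0.538; called downward without the library labelled KO 2, adjusted p = 0.0237, or 0.698 with an estimated correlation), megakaryocyte (0.595), B lymphocyte (0.595) and T and NK lymphocyte genes (0.0684) were not called with or without the block. Nor were nuclear-encoded oxidative phosphorylation (0.0684), mitochondrially encoded (0.592), ribosomal protein (0.0996), integrated stress and unfolded protein response (0.903), cholesterol synthesis (0.834) and histone genes (0.818). The eosinophil list had 2 tested genes and was not tested.

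In the gene-level test, edgeR's quasi-likelihood test called 0 of 13744 genes at an adjusted p of 0.05, with 171 at an unadjusted p under 0.05, where 687 would be met by chance. Limma voom called 0 genes (170 at an unadjusted p under 0.05), and edgeR with the block called 0 (1473 at an unadjusted p under 0.05, again with 687 by chance, 1019 of the 1473 higher in Gata2 KO). DESeq2 called 7. They were Rnf17 (log2 fold change 5.36 ± 1.09) and the homeobox gene Nkx6-2 (2.62 ± 0.51), higher in Gata2 KO, and Gm10451 (-4.79 ± 0.77), Eya4 (-4.79 ± 0.91), Dmrtb1 (-4.13 ± 0.91), Eid2 (-2.36 ± 0.53) and the adhesion molecule gene Vcam1 (-2.17 ± 0.49), lower in it, named after their values were seen. On counts simulated from this comparison, DESeq2 called 51 unchanged genes without the block and 25 with it (edgeR 11 and 13). The simulation held genes set to change and covered 13744 genes, against 23964 in the DESeq2 fit that gave the 7 calls. Of its unchanged genes, 4.66% had an unadjusted p under 0.05 by edgeR, against 171 of 13744 genes in the real fit. The simulated counts therefore cannot tell whether the 7 calls exceed chance. Nkx6-2 lay at 1.39 to 2.79 CPM in Gata2 f/f and at 8.90 to 23.2 CPM in Gata2 KO, and Vcam1 at 9.20 to 15.3 and 1.34 to 3.87 CPM, with the library labelled KO 2 on the KO side of both. Both genes were called with that library counted as KO, so its place there is no evidence for its label. With the block, DESeq2 called 211 genes, 168 higher and 43 lower, and without the library labelled KO 2 edgeR with the block called 54, 33 higher and 21 lower (both chosen after the data were seen). In 363 genes (2.64%) every KO library lay above every f/f library and in 382 (2.78%) below, where chance gives 10% for both directions together in 3 unpaired libraries against 3. Differences between the numbers can widen both groups, so these counts do not measure the paired difference. The number of lists called by camera was 3 without Gata2 f/f 1 and 4 without Gata2 KO 3.

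**Figure D3:**
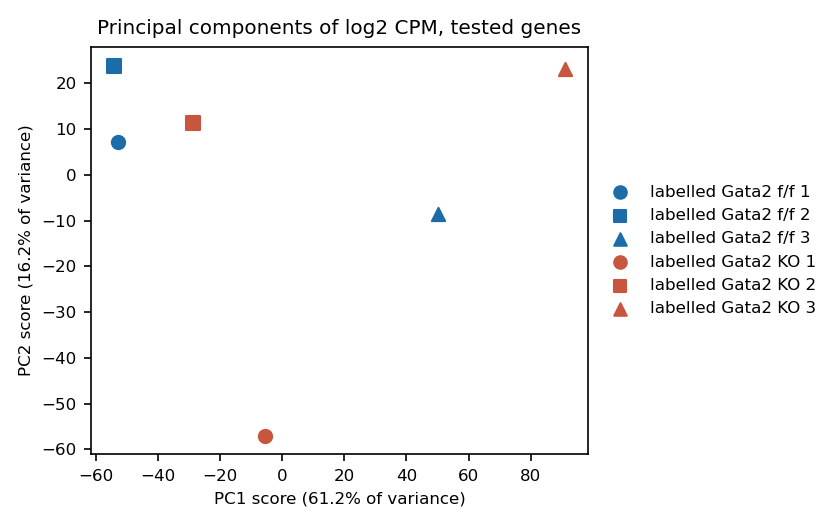
Scores of the 6 libraries on the first principal components of log2 CPM over the 13744 tested genes; the first axis carries 61.2% and the second 16.2% of the variance. The libraries numbered 3 (50.3 and 91.1 on the first axis) lie apart from the other 4 (-54.2 to -5.67), and the library labelled Gata2 KO 2 lies closer to Gata2 f/f 1 and 2 than to the other KO libraries.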

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

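The fits named as DESeq2 with the block, those without the library labelled Gata2 KO 2 together with the block, those without both libraries numbered 3, that without ribosomal RNA-derived genes and those without KO 2 with Gata2 taken out of the lists were chosen after the data were seen. The edgeR count of 0 genes was met again with the other scalings, filters and thresholds, with limma voom, with the replicate block (0 genes), without both libraries numbered 3, without the ribosomal RNA-derived genes and without each library in turn, where 72 to 988 genes had an unadjusted p under 0.05. It was 7 (2 higher, 5 lower) by DESeq2, 211 (168 higher, 43 lower) by DESeq2 with the replicate block, 54 (33 higher, 21 lower) by edgeR and 63 (40 higher, 23 lower) by DESeq2 with the block and without the library labelled Gata2 KO 2, and 8 (7 higher, 1 lower) with the block without both libraries numbered 3. The fit with 8 calls has 1 residual degree of freedom and includes the library labelled KO 2. Its higher calls included the monocyte and macrophage list genes Lyz2 (log2 fold change 2.13), Csf1r (2.63) and Mpeg1 (1.95). Its lower call was Dmrtb1 (-5.41). These genes were named after their values were seen. Gata2 kept a negative log2 fold change in all fits and passed the threshold only with the block and without the library labelled KO 2, at -2.36 by edgeR and -2.38 by DESeq2. That library was doubted for its Gata2 level, so passing without it is no evidence of Gata2 loss. Camera called 14 lists, 17 with the block, 12 to 17 with the other scaling, filters and sets of libraries named above, 3 to 20 without 1 library in turn, and 0 with an estimated correlation or with fry. Apart from the lists named in the report, the block changed no call. In the self-test on simulated counts camera called a list of 40 genes changed 1.5-fold, and edgeR missed most 2-fold changes. The simulated genes were drawn independently, without the correlation between genes on which the real list calls depend. The self-test therefore does not show how camera performs on these data.

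Named genes kept their direction in 1081 of 1102 comparisons with another setting and gene lists in 497 of 559, and the causes of the other 83 were not tested. The settings refit the same libraries, and many named genes were picked for a small p or after their values were seen. These shares therefore do not measure replication. Without both libraries numbered 3, Cx3cr1 (0.41) and Mdm2 (0.19) turned positive, as they did with the block as well (0.30 and 0.19). No other named gene compared turned in these fits. The fits without 1 library in turn had no block and left the numbers unequal between the genotypes. Leaving out 1 library in turn gave log2 ranges that crossed 0 for Cx3cr1 (-1.96 to 0.98), Mdm2 (-0.32 to 0.33), Meis1 (-0.024 to 0.37), Mki67 (-0.52 to 1.36), Fcgr4 (-0.11 to 1.86), Fcgr3 (-0.038 to 1.74), Cd14 (-0.26 to 2.26), Xaf1 (-0.13 to 2.63), Cdkn1a (-0.054 to 1.32), Pmaip1 (-0.42 to 0.061), Mcl1 (-0.079 to 0.55), Myc (-0.38 to 0.13), Itgam (-0.43 to 1.88), Lgals3 (-0.50 to 3.55) and Fth1 (-0.88 to 2.54). Ranges on one side of 0 that reached over 1.5 times from the main value included Gata2 (-2.35 to -0.032), Cd34 (-2.67 to -0.73), Kit (-1.15 to -0.17), Flt3 (-2.74 to -0.52), Bcl2 (-1.68 to -0.75), Mdm4 (-0.63 to -0.024), Fcnb (0.047 to 2.33), Prtn3 (0.27 to 0.69), Cxcr2 (1.03 to 3.61), Zbp1 (0.37 to 2.26), Bcl3 (0.47 to 1.77), Zfp36 (0.13 to 0.86), Klf2 (0.78 to 2.42), Fosl1 (0.36 to 1.72), Tnfrsf1a (0.21 to 0.72), Bax (0.18 to 0.55), Bbc3 (0.28 to 0.75), Cdkn1c (1.08 to 2.52), Chek1 (-0.81 to -0.26), Xrcc2 (-0.75 to -0.22), Pola1 (-0.72 to -0.19) and Hspd1 (-0.88 to -0.29).

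For lists that turned, the adjusted p of camera was as follows. With the replicate block it was 0.933 for the unfolded protein response and 0.669 for cholesterol, and fry gave 0.976 for MLL fusion targets. With the block and without KO 2 it was 0.824 for megakaryocyte, 0.951 for unfolded protein response and 0.237 for histone genes, each the same with Gata2 taken out of the lists. Without KO 2 and with Gata2 taken out of the lists it was 0.251 for mitochondrially encoded, 0.858 for megakaryocyte, 0.395 for unfolded protein response, 0.0920 for cholesterol and 0.104 for histone genes. Without both libraries numbered 3 it was 0.752 for pro-survival, 0.0937 for oxidative phosphorylation, 0.849 for stem and progenitor, 0.884 for unfolded protein response, 0.786 for cholesterol, 0.0519 for ribosomal protein and 0.599 for histone genes, and with the block as well 0.612, 0.0334, 0.924, 0.914, 0.636, 0.0271 and 0.612, and 0.924 for MLL fusion targets. Without 1 library in turn the lists that turned ran from 0.000910 to 0.819 (mitochondrially encoded), 0.0184 (without KO 2) to 0.880 (stem and progenitor), 0.181 to 0.833 (MLL fusion targets), 0.00206 to 0.981 (megakaryocyte), 6.73e-05 to 0.819 (cholesterol), 0.197 to 0.872 (pro-survival), 0.277 to 0.981 (unfolded protein response), 0.0316 to 0.971 (histones), 0.0237 (without KO 2) to 0.870 (mast cell), 0.0815 to 0.976 (B lymphocyte), 0.000411 to 0.554 (G1/S), 3.57e-05 to 0.849 (G2/M), 8.05e-06 to 0.870 (Myc and ribosome biogenesis), 1.07e-05 to 0.657 (oxidative phosphorylation), 0.00379 to 0.851 (antioxidant), 2.86e-05 to 0.870 (homologous recombination), 5.27e-20 to 0.505 (monocyte and macrophage), 0.000526 to 0.768 (dendritic), 0.00379 to 0.870 (stroma), 2.65e-05 to 0.768 (interferon) and 3.00e-06 to 0.829 (ribosomal proteins).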

Other observations

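All tests here were chosen after the results were seen, except the splits of the libraries for edgeR and camera and for edgeR with the block, the position of the library labelled Gata2 KO 2 on genes called without it, the thinning to equal depth and the comparison of the p53 list with random lists. The fit behind that position was itself added after the data were seen, as was DESeq2 with the block.

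In both genotypes the library numbered 3 had higher values for macrophage genes and lower values for cell cycle genes. For number 3 minus the mean of 1 and 2, with the block, camera called the monocyte and macrophage (adjusted p = 9.26e-30) and late neutrophil lists (3.91e-11) upward and the G2/M (2.12e-11) and G1/S lists (1.40e-07) downward. With an estimated correlation none was called (adjusted p = 0.324 for the first 3 and 0.383 for G1/S). With the number as a block, 1249 of 13744 genes differed between numbers (edgeR, F test at an adjusted p of 0.05). Of these, 909 were higher and 338 lower in both libraries numbered 3 than in the mean of the others of their genotype. Of 31 monocyte and macrophage genes 23 were called, all higher, as were 15 of 26 NF-kB and inflammatory genes, 12 of 28 lysosome and autophagy genes, 10 of 21 late neutrophil genes and 11 of 48 p53 targets. In the other direction, 10 of 21 cholesterol synthesis, 9 of 35 Myc and ribosome biogenesis, 8 of 40 G2/M and 4 of 39 G1/S genes were called, all lower. The mitochondrial share of the counts was 1.24% in both libraries numbered 3, above that of every other library. Camera called the mitochondrially encoded list upward in number 3 (adjusted p = 7.01e-05, and 0.324 with an estimated correlation). Of its 13 genes, 6 were called between numbers, all higher. What this share reflects, such as the quality of the cells or RNA, was not tested. Lyz2, which encodes lysozyme, had 3053 and 4245 CPM in Gata2 f/f 3 and Gata2 KO 3 and 168 to 1024 CPM in the other 4, and Fth1, the ferritin heavy chain gene, 7143 and 13464 CPM against 821 to 1703 CPM. Lgals3, which encodes galectin-3, had 833 and 1460 CPM against 44.9 to 243 CPM. Mki67, a proliferation marker, had 40.4 and 54.3 CPM against 111 to 402 CPM, and within each number it was higher in the KO library. Lyz2, Fth1, Lgals3 and Mki67 were chosen after their values were seen.

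Without the library labelled Gata2 KO 2, edgeR with the block called 54 genes between the genotypes. Of the lists fixed before the data were examined, late neutrophil genes held 8 of the 33 higher calls. For this list Fisher's exact test, taken over all 54 calls of either direction, gave an adjusted p = 2.53e-13. The test ignores correlation between genes. In the same fit camera called that list (adjusted p = 5.43e-27), but not with an estimated correlation (adjusted p = 0.716). Stem and progenitor transcription factors held 3 of the 21 lower calls, 1 of them Gata2, for which the library was left out, and did not pass the test with Gata2 taken out of the list (adjusted p = 0.0573). The neutrophil genes included Cxcr2 (log2 fold change 2.63 ± 0.38), S100a8 (2.15 ± 0.33), S100a9 (2.38 ± 0.37), Mmp9 (2.35 ± 0.39) and Lcn2 (2.06 ± 0.35). The 3 transcription factors were Zbtb16 (-3.51 ± 0.70), Gata2 (-2.36 ± 0.41) and Cbfa2t3 (-2.13 ± 0.45). Most calls were in neither list, among them the lower Angpt1 (-3.80 ± 0.48), Nebl (-3.22 ± 0.45) and Cd34 (-2.62 ± 0.41) and the higher Rnf17 (5.88 ± 0.78), Lipg (2.58 ± 0.37) and Nkx6-2 (3.01 ± 0.45). This fit has 1 residual degree of freedom and rests on the pairs numbered 1 and 3. The genes named were chosen after their values were seen. With all 6 libraries and the block, DESeq2 called 9 of 21 late neutrophil, 7 of 31 monocyte and macrophage and 3 of 28 lysosome genes, all higher in Gata2 KO.

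With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For edgeR the real split gave 0 genes, a count that any split reaches, so the comparison tests nothing for it, and the highest other gave 449. For DESeq2, 5 of 10 splits gave at least the real 7 genes and the highest other gave 1588. For camera, 6 of 10 gave at least the real 14 lists and the highest other gave 28. The split with 449 and 1588 genes set Gata2 f/f 1, f/f 2 and the library labelled KO 2 against f/f 3, KO 1 and KO 3, which points to a structure of the samples other than the labels. The same split parts the shares of ribosomal RNA-derived reads, at 7.01%, 1.25% and 5.95% against 0.283%, 0.288% and 1.02%. Whether these shares bear on the split was not tested. Of the 4 splits that part all 3 pairs, again too few, 1 (the real one) reached 211 genes by DESeq2 with the block, the highest other giving 40, and 1 (the real one) reached 1473 genes at an unadjusted p under 0.05 in edgeR with the block, the highest other giving 698.

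The library labelled Gata2 KO 2 had Gata2 and Cd34 at the f/f level. A swap of labels with an f/f library is argued against, since the lowest f/f library had 3.39 times the Gata2 CPM of the highest other KO library. On the 54 genes called without it, its median position between f/f 1 and 3 (set to 0) and KO 1 and 3 (set to 1) was -0.15, against -0.36 for f/f 2. The difference was 0.20 (95% bootstrap interval over genes 0.0042 to 0.40). The 54 genes were chosen for their difference between the libraries that set 0 and 1, and include Gata2 and Cd34. A KO library outside that choice could also fall short of 1. The position therefore does not decide whether a single f/f library carries a KO label. Of the 54 genes, 3 were past halfway to KO 1 and 3 (Myh15, Gm10451 and Nkx6-2, at 1.00, 0.78 and 0.74) and 51 were not, while 40 lay beyond f/f 2 in the KO direction. Over all genes the KO minus f/f differences of numbers 1 and 2 correlated at 0.29 (0.09 for 1 and 3, 0.13 for 2 and 3). Numbers 1 and 3, whose labels are not in doubt, correlated least, so these values do not decide whether KO 2 is an f/f library. A KO culture in which cells kept Gata2 (1.29 times the highest f/f CPM) cannot be told apart from a single wrong label, since both place Gata2 at the f/f level and reads per exon were not analysed here.

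The libraries numbered 3 stood apart on the first principal component. Their higher depth is argued against: with every library thinned to 17138687 counts, 95.8% of the 1249 genes were called again. Ribosomal RNA reads in CT010467.1, Gm26917, Gm23935 and Lars2 took 0.283% and 1.02% of their counts against 0.288% to 7.01% in the other 4, so 1 of the 2 shares lay inside that range. Of the other 4, only Gata2 KO 1 (0.288%) lay below the 1.02% of Gata2 KO 3. Gata2 f/f 1 (7.01%), f/f 2 (1.25%) and the library labelled KO 2 (5.95%) lay above both shares. The range therefore cannot decide on ribosomal RNA carry-over, which stays open. A stronger p53 response stays open as a hypothesis: the median number-3 difference of 48 p53 targets, 0.51, lay at percentile 100 of 10000 random lists matched on expression. Random lists ignore correlation between genes. Camera gave the p53 list an adjusted p = 0.000295 in number 3, and 0.384 with an estimated correlation. The mean of the monocyte list was larger (2.37), so the p53 list did not stand alone. What the numbers stand for is not given in the labels, and no biological explanation beyond this was tested.

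The higher myeloid maturation genes in the libraries labelled KO may reflect their place on the same axis, Gata2 loss, or another mix of cells. By label, Cre goes together with Gata2 loss and was not separated from it. If the axis were the whole cause, the G2/M list would follow the monocyte list in its number-3 proportion; it lay 0.39 and 0.30 above that in the pairs numbered 1 and 2 and 0.26 below it in that numbered 3 (log2; mean 0.14 ± 0.20, SE over 3 pairs). In pairs 1 and 2 the monocyte list differed by 1.12 and 1.06 with G2/M at 0.01 and -0.06. With pairs of opposite sign, this and Gata2 loss cannot be told apart. The test took a lower share of the main cell type to raise late neutrophil and mast cell genes alike. The mast cell list holds Kit, however, which the Gata2 f/f cells expressed, so that list may fall with the main cells. The difference between the lists was 1.30 ± 0.70 (SE over 3 pairs), with 0.09 in the pair numbered 2 and 2.50 in the pair numbered 1. It cannot settle the mix of cells, which stays open as well. The genotype stays among the open explanations, with the label of KO 2 in doubt.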
